A study of Mus musculus with 2 samples.

How the data were processed

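Polyadenylated RNA from brain tissue of male C57BL/6J mice aged 14 weeks was sequenced in 2 libraries, both wild type per the labels. The position of one tissue sample along the anterior-posterior axis was matched to anterior slices, and that of the other to posterior slices, imaged by MERFISH, a method that counts RNA molecules in tissue sections by microscopy. Each position had 1 library, so there were no replicates and no spread between animals could be measured. The tissue position, the library and the quantification pipeline differed together and cannot be separated by the design. Whether the tissue came from different animals is not given in the sources used here.

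For the anterior library the authors deposited FPKM values per gene (fragments scaled to gene length and to a library total), with gene lengths, coordinates and biotypes. The reads were aligned with HISAT2 2.0.5 to build mm10, per the submitters' processing notes. The program that counted fragments per gene, its annotation and its use of strand are not given in the sources used here. For the posterior library the authors deposited estimated counts (fragments, which need not be whole), TPM, length and effective length per transcript. These were made with Salmon against a GENCODE transcript set, per the labels' protocols, and with build mm10, per the submitters' processing notes. The version and options of Salmon are not given in the sources used here. The deposited posterior table is called FPKM but its value columns hold TPM and estimated counts, and the TPM column sums to 1000000.

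The planned analysis assumed FPKM in both libraries. Posterior FPKM was therefore computed from the deposited estimated counts by scaling them to effective length and to the total of estimated fragments, and summed over the transcripts of a gene. The posterior FPKM came to 0.609 of the TPM. Anterior fragments per gene were recovered from the deposited FPKM: the product of FPKM and gene length was a whole multiple of 27.4 for 100% of the 54532 genes within a tolerance of 0.001, with a largest deviation of 7.99e-08. The recovered total was 43558839 fragments. The denominator implied by the FPKM scale was 36521279, or 0.838 of that total, so the deposited FPKM were not scaled to the recovered sum over genes. Which total was used is not known. The posterior table held 147138183 estimated fragments in 140992 transcripts of 54347 genes. In a gene of 1 kb, 1 fragment was worth an FPKM of 0.0274 in the anterior library and, per 1 kb of effective length, 0.00680 in the posterior library. A floor of 3 fragments corresponded to 0.0821 and 0.0204. Intervals are 95% and cover counting error only, since fragments without molecular identifiers are not independent molecules.

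Genes were joined by identifier without version, which matched 53055 genes holding 99.9% of the anterior fragments and more than that share, 99.95%, of the posterior fragments. In 27 rows the anterior gene name had been turned into a calendar date, so gene symbols were taken from the posterior table. The comparison used 13339 genes annotated protein coding with an FPKM of at least 1 in either library. The difference was log2 of posterior over anterior FPKM with a pseudocount of 0.5, centred on the median over those genes, which was 0.63. A log2 difference on this scale understates the change of low genes. A second scale, planned before the data were examined, used fragments scaled to the total in protein-coding genes, with the same pseudocount and centring (shift 0.00298). It uses no gene length and is called the fragment share. Folds with intervals are ratios of fragment shares without a pseudocount, with exact Clopper-Pearson limits from the counts in both libraries. Where the anterior count was 0, the fold is a lower bound against 3 fragments.

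With 1 library per position no p-value was computed. Gene lists were fixed before the data were examined: 23 lists of regional, cell type and activity markers, and 3 technical lists of ribosomal protein, mitochondrially encoded and replication-dependent histone genes. Each list with at least 3 measured members was described by the median of its members and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentiles describe these libraries and do not generalise to the positions. A list is said to lie outside the range of random lists below the 2.5 or above the 97.5 percentile. Transcript shares were the percent of a gene's summed FPKM in each transcript, for genes with an FPKM of at least 1 and at least 2 annotated transcripts. The 6 transcript lists were set against random lists matched on FPKM and on the number of annotated transcripts. Salmon's estimation error per transcript was not used here, so transcript shares carry no interval.

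The genes named were chosen by a rule fixed in advance: the 10 genes with the highest FPKM in each library; the 10 highest and 10 lowest differences among protein-coding genes with an FPKM of at least 5 and the same sign on both scales, without predicted, ribosomal, histone and mitochondrial genes; the 3 largest differences and the member of each list with the highest FPKM in either library; the 3 lowest leading-transcript shares and the highest of each transcript list; 5 genes that check sex; and the 10 genes with most transcripts at 10% or more among those with an FPKM of at least 20. Other genes are given as members of their lists or were chosen after their values were seen, which is stated there. Some genes that the rule takes are not reported here.

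GENCODE release M21, an annotation of the mm10 genome that may differ from those the authors used, gave exon overlaps and transcript structures. Its gene coordinates equalled those of the anterior table in 98.3% of joined genes and its exonic length in 98.0%. It held 139172 of the posterior transcript identifiers with their version, or 98.7%. For each gene the percent of exonic bases under exons of another gene was computed, and the percent of its 100-base words, 1 in 8 sampled, that also occur on the same strand in a transcript of another gene. Coordinates are those of the anterior table and count from 1.

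Alternatives were pseudocounts of 0.1 and 1, an FPKM of at least 5 or no filter, the fragment share, protein-coding transcripts only, no centring, a 4-fold rule, other FPKM minimums for the genes listed, and for transcripts a gene FPKM of at least 5, shares of fragments in place of FPKM, and minimum shares of 5% and 25%. In the comparison, protein-coding transcripts only restricts the posterior library alone, since anterior values are per gene. Restriction to the 7345 measured genes with no exonic overlap and no shared words, by FPKM and by fragment share and centred on their own median, was added after seeing the data. The computation was tested on simulated data drawn from the anterior library at the posterior depth, over 12030 genes: the 2-fold rule found 100% of the 50 genes set 4-fold higher, 94% of the 50 set 4-fold lower, 100% of the 50 set 3-fold higher and 90% of the 50 set 3-fold lower, and 0% of the 11830 unchanged genes. Of 100 lists of 12 unchanged genes, 5 lay outside the middle 95% of random lists. Changes were set only in genes above a minimum count of anterior fragments, so recovery in low genes was not tested. The simulated libraries shared gene lengths and counting, and only the posterior counts were drawn. These rates therefore cover counting error of the posterior library only. They do not cover differences between the real pipelines and give no error rate for the real comparison. Drawn transcript shares of 12666 genes were recovered within 2 percentage points for 85.0%. Counts were drawn per transcript, so the assignment of fragments among the transcripts of a gene was not tested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.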

Results

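Bulk RNA sequencing of mouse brain tissue gave 1 library from an anterior and 1 from a posterior position, both labelled as male C57BL/6J mouse tissue at 14 weeks of age. The series concerns imaging of transcript isoforms in single cells of tissue sections, and per the labels the tissue was matched in position to imaged slices. The anterior library held 43558839 fragments over genes and the posterior library 147138183 estimated fragments over transcripts, 3.38 times as many. An FPKM of at least 1 was reached by 13991 genes in the anterior and by 15092 in the posterior library, of which 12047 and 13136 were protein coding. There were no replicates, and each position was quantified by its own pipeline. Values below therefore compare these 2 libraries and not the positions.

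By FPKM a mitochondrial gene led each library, but the leading genes were not the same. In the anterior library mt-Co1, a subunit of cytochrome c oxidase, had the highest FPKM at 11960, followed by mt-Cytb at 6686, mt-Nd1 at 6316, the microRNA gene Gm23935 at 6179, which spans 57 bases, and mt-Nd2 at 3643. The other 5 of the leading 10 were mt-Rnr1, mt-Nd4, mt-Rnr2, mt-Nd5 and mt-Nd6, between 2771 and 2211. In the posterior library mt-Atp8, a subunit of ATP synthase, led with 43209, followed by the ribosomal RNA gene CT010467.1 at 31309, the short neuronal noncoding RNA Bc1 at 26919, mt-Atp6 at 11903 and mt-Co1 at 10659. The unprocessed pseudogene Gm28661 (9762), mt-Co3, mt-Nd3, mt-Nd4l and mt-Nd1 (5536) completed its leading 10. Scaling to length raises short genes in this ranking. Anterior FPKM were scaled to gene length and posterior FPKM to effective length, so the rankings are not on a like scale. In the posterior library mt-Atp8 and Bc1, which span 204 and 168 bases, had effective lengths below that span. They held 145923 and 33837 posterior fragments, fewer than mt-Co1 with 1972898. Of the posterior leading 10, CT010467.1 held the most fragments, 7195416 or 4.89% of the total. Mitochondrially encoded protein-coding genes took 3.79% of anterior fragments (95% Wilson interval 3.79 to 3.80) and 4.35% of posterior fragments (4.34 to 4.35). Ribosomal protein genes took 0.843% (0.841 to 0.846) and 0.889% (0.887 to 0.890).

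Genes that differ between the sexes had the male pattern in both libraries, as both are labelled. Xist, the RNA that silences an X chromosome in females, had 5 fragments in the anterior and 19 in the posterior library. The Y-linked genes were present in both: Ddx3y had an FPKM of 16.0 and 16.7, Eif2s3y of 12.8 and 35.0, Kdm5d of 2.21 and 7.51, and Uty of 2.27 and 6.72.

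Across the 13339 protein-coding genes compared, the libraries correlated with Pearson's r = 0.85 and Spearman's rho = 0.86 on the log2 FPKM scale, and with 0.92 and 0.95 on the fragment share scale. These are correlations across genes, which are not independent replicates. Relative to the median gene, 1933 genes were at least 2-fold higher in the posterior library and 949 in the anterior library, so 67.1% of the genes past the rule lay on the posterior side. Of the 7345 genes without exonic overlap or shared sequence, 8.92% were at least 2-fold higher in the posterior and 9.42% in the anterior library with the same FPKM scale and centring. On the fragment share scale the counts were 1092 and 246, or 81.6% on the posterior side. The FPKM difference correlated across genes at 0.63 with the ratio of the anterior gene length to the posterior effective length, and the fragment share difference at -0.034. By fragment share the genes without overlap or shared sequence gave 350 and 142 with the centring of all genes, and 423 and 135 when centred on their own median. By FPKM with the latter centring they gave 929 and 368.

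The 10 genes that stood highest in the posterior library by the fixed rule were Ttr, Pmch, Gapdh, Mt2, Hcrt, Tomm6, Ube2v1, Rnasek, Lars2 and Prrt2. Ttr encodes transthyretin, the thyroid hormone carrier made in quantity by the choroid plexus (chromosome 18, 20665250 to 20674324). It had 4 anterior and 83721 posterior fragments, an FPKM of 0.0898 against 633, and a fragment share 6606-fold higher (95% interval 2580 to 24245). Pmch and Hcrt, the precursors of melanin-concentrating hormone and of the orexins, belong to neurons of the lateral hypothalamus. Pmch (chromosome 10, 88091072 to 88092375) had an FPKM of 0.183 against 411, and Hcrt (chromosome 11, 100761069 to 100762931) of 0.366 against 212, with a fragment share 295-fold higher (160 to 615). Gapdh, the glycolytic enzyme, had an FPKM of 4.45 against 1426, a fragment share 107-fold higher (98.9 to 115). Of its words 20.03% occurred in annotated transcripts of other genes, and copies outside the annotation were not searched. Whether the contrast in Gapdh comes from the counting was not tested. Mt2, Tomm6, Ube2v1, Rnasek, Prrt2 and Pmch each had between 58.1% and 92.4% of their exonic bases under exons of another gene on either strand. Their counts may therefore depend on how shared fragments were assigned and on the use of strand. In Lars2, the mitochondrial leucyl-tRNA synthetase, 99.2% of the posterior FPKM lay in 1 transcript, Lars2-209, annotated as subject to nonsense mediated decay. With protein-coding transcripts alone in the posterior library, the log2 difference of Lars2 was -0.48 in place of 6.20. The anterior value covers the whole gene and could not be restricted, so the sides are not alike.

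The 10 genes that stood highest in the anterior library were Cox5b-ps, Hipk4, Klhl34, Il4, Pter, Eno1b, Csnk2a3, Fam205c, Cabyr and Ccl21b. Their anterior FPKM lay between 5.79 (Ccl21b) and 42.8 (Cox5b-ps), and their posterior FPKM between 0 (Ccl21b) and 1.12 (Pter). Csnk2a3, Eno1b and Ccl21b shared 83.0%, 75.3% and 100% of their words with other genes, and Cox5b-ps 25.8%. Pter, a phosphotriesterase-related gene (chromosome 2, 12924041 to 13003455), had 6655 anterior and 279 posterior fragments, and a fragment share 75.6-fold higher in the anterior library (67.0 to 85.5). Il4, which encodes the cytokine interleukin 4 (chromosome 11, 53602982 to 53618669), had 581 anterior fragments and 1 posterior fragment, a ratio of 1841 (329 to 72835).

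Markers of excitatory neurons of the isocortex were higher in the anterior library. The median log2 difference of the 15 measured genes was -1.09, and 9 of them were at least 2-fold higher in the anterior library and 0 in the posterior library. Fezf2, a transcription factor of deep-layer projection neurons, had an FPKM of 17.8 against 8.04, a fragment share 2.75-fold higher in the anterior library (2.59 to 2.92). Neurod6, a transcription factor of cortical excitatory neurons, had 62.8 against 28.9, a share 1.97-fold higher (1.90 to 2.04). The most abundant member, the vesicular glutamate transporter Slc17a7, had 332 against 324, which is a centred difference of -0.66. The list lay at percentile 0 of random lists on both scales, and its median was -0.73 on the fragment share scale, where 5 genes were at least 2-fold higher in the anterior library and 0 in the posterior library.

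Markers of thalamus and hypothalamus were higher in the posterior library. Of 10 thalamic genes 9 were at least 2-fold higher there, with a median log2 difference of 2.23 and a percentile of 100. Prkcd, a protein kinase C of thalamic relay neurons (chromosome 14, 30595354 to 30626210), had an FPKM of 1.53 against 99.9, a fragment share 32.4-fold higher (28.95 to 36.3). Tcf7l2, a transcription factor of thalamic neurons (chromosome 19, 55741810 to 55933654), had 0.53 against 22.2, and Ntng1 had 2.54 against 27.7. Of 12 measured hypothalamic genes 11 were at least 2-fold higher in the posterior library, with a median of 2.19 and a percentile of 100. Besides Pmch and Hcrt, the vasopressin gene Avp had 0.19 against 41.6 (4 and 1777 fragments), the oxytocin gene Oxt had 0.102 against 19.98, and the proopiomelanocortin gene Pomc had 1.27 against 10.6. The galanin gene Gal had 0 anterior and 788 posterior fragments, and its share was at least 82.9-fold higher, against a floor of 3 anterior fragments. On the fragment share scale the medians were 2.96 for thalamus and 3.12 for hypothalamus, and the latter kept that value with Gal at its bound.

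Hippocampal and striatal markers also stood higher in the posterior library. Of 10 hippocampal genes 8 were at least 2-fold higher, with a median log2 difference of 1.32 (percentile 99.95), or percentile 95.5 at an FPKM of at least 5, where 7 members were left. C1ql2, expressed by dentate granule cells, had an FPKM of 0.233 against 9.43, a share 44.1-fold higher (27.5 to 75.9), Zbtb20 had 3.03 against 23.6, and Dsp had 0.017 against 2.27. Wfs1, the most abundant member, had 32.8 against 34.0. Of 16 genes of striatal medium spiny neurons 7 were at least 2-fold higher in the posterior library, with a median of 0.80 (percentile 99.78). The 7 included Adora2a, an adenosine receptor, with 1.31 against 11.4, Syndig1l with 0.862 against 7.63, Penk with 23.9 against 130 and the dopamine receptor Drd2 with 0.624 against 4.53. Drd1, the dopamine receptor of the other main class of these neurons, had 5.77 against 7.92, a centred difference of -0.21. With only the 11 members without overlap or shared sequence the striatal median was 0.54 by FPKM, inside the range of random lists (percentile 94.7), and 0.76 by fragment share (percentile 100). Of 5 measured genes of midbrain dopaminergic neurons 3 were at least 2-fold higher in the posterior library, and 1 in the anterior library by FPKM but 0 by fragment share. Aldh1a1 had 7.02 against 43.0, Nr4a2 3.17 against 14.2 and Ddc 1.57 against 6.81, with a list median of 1.19 (percentile 98.7), while the dopamine transporter Slc6a3 stayed below an FPKM of 1 in both libraries. The midbrain list lay inside the range of random lists without a filter (median 0.22 over 10 members, percentile 93.2) and at an FPKM of at least 5 (3 members, percentile 93.3). Of 3 measured cholinergic genes, of which 1 was at least 2-fold higher in the posterior library, Ecel1 had 0.79 against 13.7, Chat 0.099 against 1.15 and Slc5a7 0.281 against 1.57, with a median of 0.83 at percentile 78.2. By fragment share all 3 were at least 2-fold higher there, with a median of 2.17 at percentile 96.0.

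Choroid plexus and ependymal markers stood higher in the posterior library as well. All 10 choroid plexus genes were at least 2-fold higher in the posterior library on both scales. Their median log2 difference was 2.47 by FPKM and 3.67 by fragment share, both at percentile 100. Besides Ttr, Clic6 had an FPKM of 0.063 against 6.38, a share 112-fold higher (59.1 to 246), and Kl, the hormone receptor component klotho, had 0.296 against 9.23. Of 6 ependymal genes 5 were at least 2-fold higher in the posterior library, with a median of 2.03 (percentile 99.93), or percentile 93.1 at an FPKM of at least 5, where 3 members were left. Ccdc153 had 1 anterior and 593 posterior fragments, a ratio of 187 (33.5 to 7405). Rarres2 had an FPKM of 0.546 against 13.2. Tmem212 had 0 anterior and 225 posterior fragments, at least 23.7-fold higher. Of 7 measured genes of meningeal fibroblasts 3 were at least 2-fold higher in the posterior library, with a median of 0.45 (percentile 88.1). Igf2, which choroid plexus also expresses, had 0.115 against 25.7, with 64.5% exonic overlap, Dcn had 1.28 against 7.72 and Ptgds had 255 against 848. Of 5 blood genes Hba-a2 had 14.3 against 205 and Hbb-bs had 71.1 against 269, at a list median of 0.66 (percentile 93.7, and 98.2 by fragment share), and 4 of the 5 overlap or share sequence with other genes over more than 50%. Alas2 had 1.88 against 1.38.

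**Figure D1:**
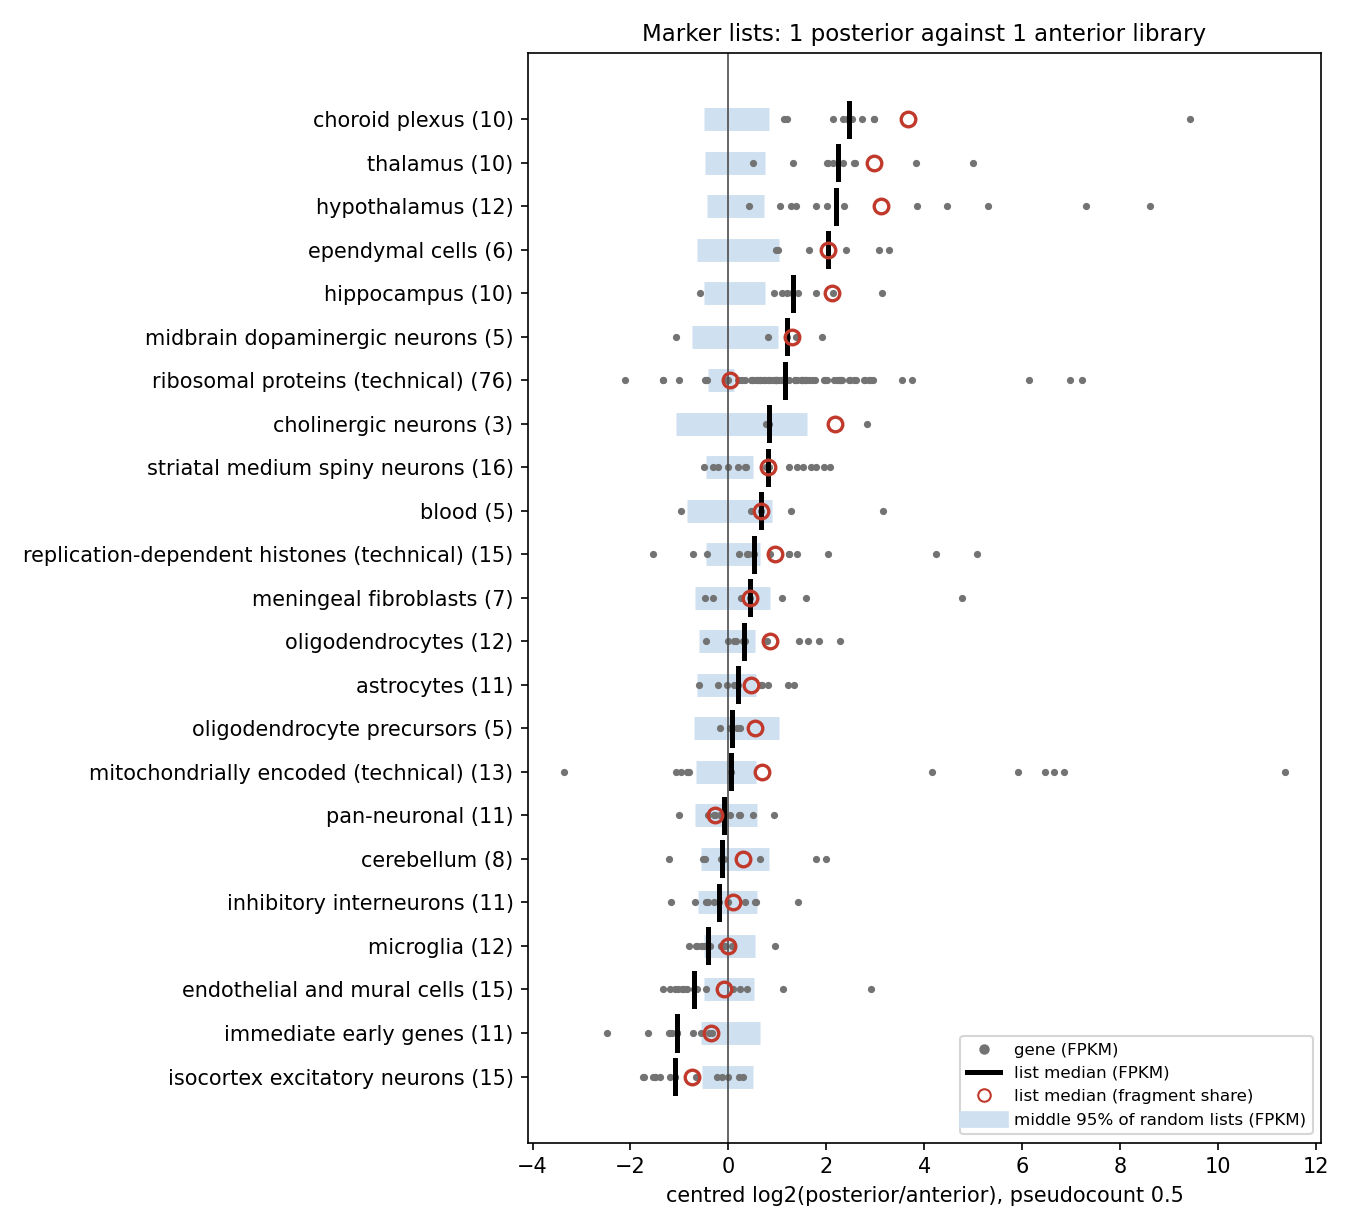
Centred log2 difference of each measured gene (grey points), list median by FPKM (black bars), list median by fragment share (red circles) and middle 95% of random lists by FPKM (blue bands), for lists with at least 3 measured members, whose number stands in parentheses. Choroid plexus (median 2.47), thalamus (2.23) and hypothalamus (2.19) lie farthest to the posterior side and isocortex excitatory neurons (-1.09) farthest to the anterior side, while ribosomal proteins lie at 1.15 by FPKM and at 0.037 by fragment share.

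Of 12 oligodendrocyte genes 4 were at least 2-fold higher in the posterior library, with a median log2 difference of 0.33 (percentile 90.9) by FPKM and 0.84 (percentile 100) by fragment share. Mbp, the myelin basic protein, had an FPKM of 208 against 1554, a share 1.84-fold higher (1.83 to 1.86), Mobp had 82.5 against 463 and Aspa had 2.88 against 15.6. The 5 genes of oligodendrocyte precursors, among them Pdgfra (5.82 against 10.5), Gpr17 (7.41 against 10.3) and Cspg4 (2.33 against 4.65), all lay within 2-fold, with a median of 0.083 at percentile 53.3. Of 11 astrocyte genes, Gfap (23.4 against 85.1) and Gja1 (15.2 against 60.8) were at least 2-fold higher in the posterior library, with a median of 0.20 by FPKM (percentile 83.1) and 0.46 by fragment share (percentile 99.99). Gjb6 had 15.3 against 42.6, and Aldoc, the member with the highest FPKM in either library, 215 against 375. Slc1a2, a glutamate transporter, had 313 against 317. All 12 microglial genes lay within 2-fold, with a median of -0.42 (percentile 5.5). Among them Trem2 had 2.41 against 8.19, but a fragment share difference of -0.25, Cx3cr1 12.3 against 10.9 and Tmem119 8.78 against 8.60. The endothelial and mural list had a median of -0.71 (percentile 0.16) by FPKM and of -0.097 (percentile 15.1) by fragment share. In it Itm2a had 33.4 against 20.1 and Kcnj8 1.90 against 1.12, while Tagln (0.0689 against 6.14) has 67.9% exonic overlap, and Ly6c1, the member with the highest FPKM in either library, had 16.4 against 55.7.

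The pan-neuronal list had a median of -0.092 (percentile 58.0) by FPKM and of -0.28 (percentile 9.05) by fragment share. Tubb3 had 210 against 161, a share 1.21-fold higher in the anterior library (1.19 to 1.23). Syp had 185 against 409, a share 1.20-fold higher in the posterior library (1.19 to 1.21). Map2 had 93.1 against 276, but a share ratio of 1.00 (0.992 to 1.01). Snap25 had 533 against 965, but a share 1.71-fold higher in the anterior library (1.70 to 1.72). Inhibitory interneurons had a median of -0.18 (percentile 38.8) by FPKM and of 0.090 (percentile 88.6) by fragment share. Within that list Npy had 134 against 92.2, a share 2.32-fold higher in the anterior library (2.20 to 2.43), Adarb2 had 1.85 against 9.23, Vip had 16.95 against 16.3 and Sst had 240 against 272. Immediate early genes, which neuronal activity induces, were higher in the anterior library, with a median log2 difference of -1.06 and 7 of 11 genes at least 2-fold higher there. Npas4 had 7.18 against 1.63, a share 3.59-fold higher (3.25 to 3.96), Egr4 had 16.5 against 7.97, Ier2 had 6.66 against 4.30 and Egr1 had 58.2 against 39.3. By fragment share the median of that list was -0.36 (percentile 0.1) and 1 gene, Npas4, was at least 2-fold higher.

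None of the 15 genes of hindbrain and serotonergic neurons reached an FPKM of 1 in either library. Hoxa2, Hoxa3, Hoxa4, Hoxa5, Hoxb2, Hoxb3, Hoxb5, Hoxc4 and Hoxd3 had 0 fragments in both, which allows up to 3 fragments, and the serotonergic gene Tph2 had an FPKM of 0.333 and 0.285. Of 12 cerebellar genes 8 were measured, with a median of -0.13 (percentile 27.0) by FPKM and of 0.30 (percentile 92.0) by fragment share, but Gabra6, a receptor subunit of cerebellar granule cells, had 0 fragments in both, and Pcp2 had 4 and 11. The measured genes of that list included Zic1 (3.12 against 18.9), Cbln1 (1.99 against 14.9), Car8 (4.01 against 2.52) and Itpr1 (65.8 against 91.3), which other brain regions also express. By fragment share Itpr1 was 1.61-fold higher in the anterior library (1.59 to 1.62). Of 7 olfactory bulb genes only Doc2g was measured (0.299 against 1.74), and of 6 pituitary genes only Cga (0 against 1.70, or 0 and 100 fragments, at least 10.5-fold higher), so neither list was given a median.

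Technical lists behaved differently on the 2 scales. The median of 76 ribosomal protein genes was 1.15 by FPKM, with 44 genes at least 2-fold higher in the posterior library, and 0.037 by fragment share, with 8. The list lay outside the range of random lists on both scales, but inside it by fragment share with only the 4 members without overlap or shared sequence (percentile 83.7). Rpl24 had an FPKM of 0.611 against 257, Rps10 of 1.36 against 363, Rpl13a of 5.44 against 651 and Rps21 of 161 against 1198. The 13 mitochondrially encoded genes did not move together: mt-Atp8, mt-Atp6, mt-Co3, mt-Nd4l, mt-Nd3 and mt-Co2 stood 4.17 to 11.37 higher in the posterior library on the log2 FPKM scale, while mt-Cytb, mt-Nd1, mt-Nd2, mt-Nd5 and mt-Co1 lay between -1.07 and -0.80, mt-Nd4 at 0.053 and mt-Nd6 at -3.35. Their list median of 0.053 (percentile 73.5) is that of mt-Nd4 and describes neither part, and by fragment share it was 0.69 (percentile 100). The median of 15 histone genes was 0.53 (percentile 95.02). H2ac19 and H2ac18 had 0 anterior and 915 and 626 posterior fragments, at least 96.3-fold and 65.9-fold higher, and overlap another gene over 100% of their exonic bases. H4c8 had an FPKM of 0.583 against 6.39. H1f10, the most abundant member, with 16.5 against 37.4, is not replication dependent but was taken in by the name pattern.

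**Figure D2:**
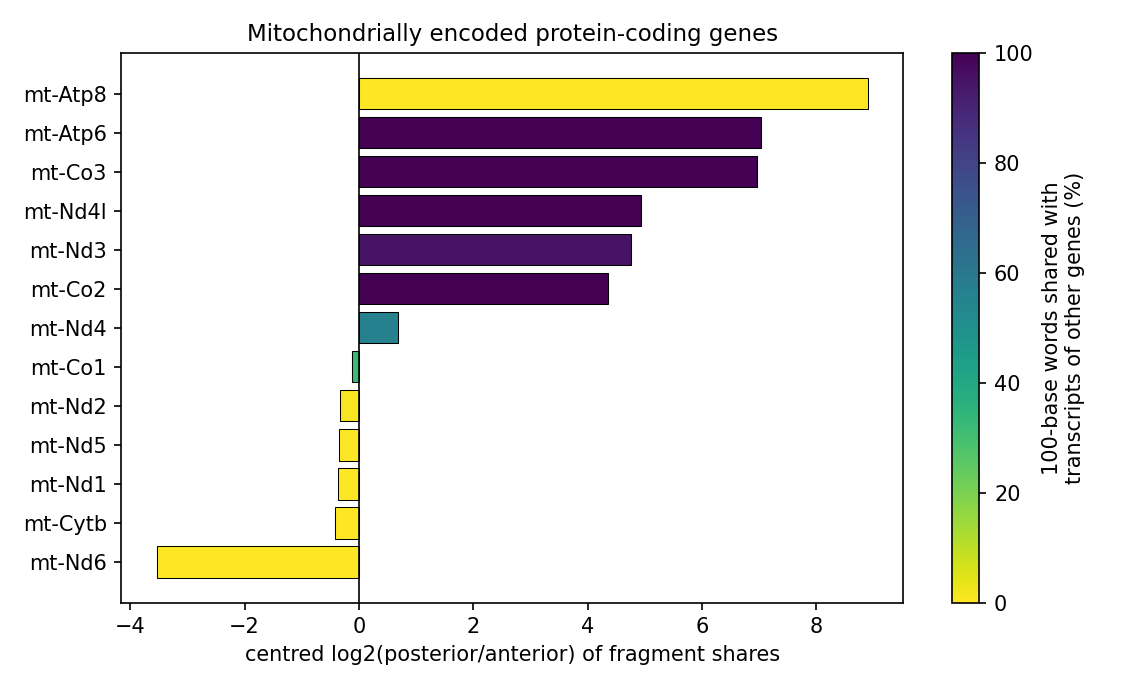
Centred log2 ratio of posterior to anterior fragment shares for the 13 mitochondrially encoded protein-coding genes, coloured by the percent of their 100-base words that occur in transcripts of other genes. The 5 genes with at least 95% shared words lie between 4.35 and 7.04, and mt-Atp8 and mt-Nd6, with 0%, lie at 8.90 and -3.53.

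Transcripts were resolved in the posterior library alone, so the transcript results describe that library and compare no positions. Of 12602 genes with at least 2 annotated transcripts, 8624 (68.4%) had 2 or more transcripts at 10% or more of the gene, and 4022 (31.9%) had 3 or more. The leading transcript took a median of 67.9% of the gene (quartiles 49.0% and 87.5%), and in 2730 genes it took at least 90%. By fragments in place of FPKM, 6714 genes (53.3%) had 2 or more transcripts at 10% or more, and the median leading share was 82.0%. With protein-coding transcripts only, 5855 of 9410 genes (62.2%) had 2 or more. Of the summed FPKM of protein-coding genes, 90.2% lay in transcripts annotated protein coding, 4.83% in retained-intron transcripts, 2.88% in processed transcripts and 2.00% in transcripts subject to nonsense mediated decay. By fragments the shares were 93.2%, 3.07%, 1.11% and 2.42%.

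In 15 of 17 genes of synaptic adhesion and scaffolding 2 or more transcripts reached 10%, and the median leading share was 41.0%, at percentile 8.21 of matched random lists. Dlg1 and Ptprs had leading shares of 26.0% and 27.2%, and Nlgn2 had the highest of the list, 86.5%. Homer1, a postsynaptic scaffold, was divided among Homer1-203 (30.1%), Homer1-207 (24.4%), Homer1-202 (20.5%) and Homer1-204 (20.4%). In M21 Homer1-203 and Homer1-202 have coding parts of 1098 and 1110 bases, and Homer1-207 and Homer1-204 of 579 and 558 bases. Of 18 genes of cytoskeleton, axon and membrane traffic 15 had 2 or more such transcripts, with a median leading share of 40.3% (percentile 6.52). Macf1, Ank3 and Ank2 had the lowest, 18.1%, 19.7% and 24.1%, and App the highest, 90.3% in App-201 with a coding part of 2085 bases. Ank2 was led by the retained-intron transcript Ank2-216, of 1 exon, and Ank3 by Ank3-243, a model of 534 bases. In Mapt, the microtubule-associated protein tau, Mapt-204 took 72.3%.

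Among receptors, channels and synaptic kinases 15 of 21 genes had 2 or more such transcripts, with a median leading share of 48.5% (percentile 26.5). Camk2g (24.4%), Grin1 (29.4%) and Atp2b1 (35.9%) had the lowest leading shares and Camk2a (90.7%) the highest. Gria2, an AMPA receptor subunit, was divided among Gria2-202 (48.5%) and Gria2-201 (22.5%), both with a coding part of 2649 bases but lengths of 4026 and 10371 bases, and the retained-intron transcript Gria2-206 (16.6%). Snap25-201 took 89.9% of Snap25 (TPM 1424) and Snap25-202 took 9.86%, both with a coding part of 618 bases.

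Of 6 myelin genes 4 had 2 or more such transcripts, and the median leading share was 63.9% (percentile 11.5). Mbp-211, with a coding part of 384 bases, took 62.9% of Mbp (TPM 1605) and Mbp-212, with 507 bases, took 22.2%. Mag was led by Mag-203 with 43.3%. Mobp was led by Mobp-204 (74.7%), which is annotated as subject to nonsense mediated decay, and Mog-201 took 93.9% of Mog. All 9 genes of trophic factors and their receptors had 2 or more such transcripts, with a median leading share of 48.4% (percentile 63.1). Bdnf was led by Bdnf-205 (35.5%), Ntrk3 had a leading share of 40.5%, Nrg1 was led by Nrg1-203 (40.7%) and Nrg3 by Nrg3-201 (65.5%). In Ntrk2, the receptor of brain-derived neurotrophic factor, Ntrk2-202 with a coding part of 1428 bases took 48.4% and Ntrk2-201 with 2463 bases took 33.2%. Of 19 measured RNA-binding splicing regulators 18 had 2 or more such transcripts, with a median leading share of 45.7% (percentile 12.2). Celf2 (25.4%), Mbnl2 (28.6%) and Rbfox3 (30.2%) had the lowest leading shares and Elavl3 (89.5%) the highest. By FPKM over all transcripts none of the 6 lists lay outside the range of matched random lists. Synaptic adhesion and scaffolding lay below it with protein-coding transcripts only (45.5%, percentile 1.31) and by fragments (47.4%, percentile 0.73), and cytoskeleton, axon and membrane traffic did so by fragments (47.6%, percentile 0.75). Among genes with an FPKM of at least 20, the genes with most transcripts at 10% or more included Dcaf11, Iffo1, Flna, Mapkap1, Glt8d1, Chka, Synj1, Slc25a36 and Usf1, with 6 each.

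**Figure D3:**
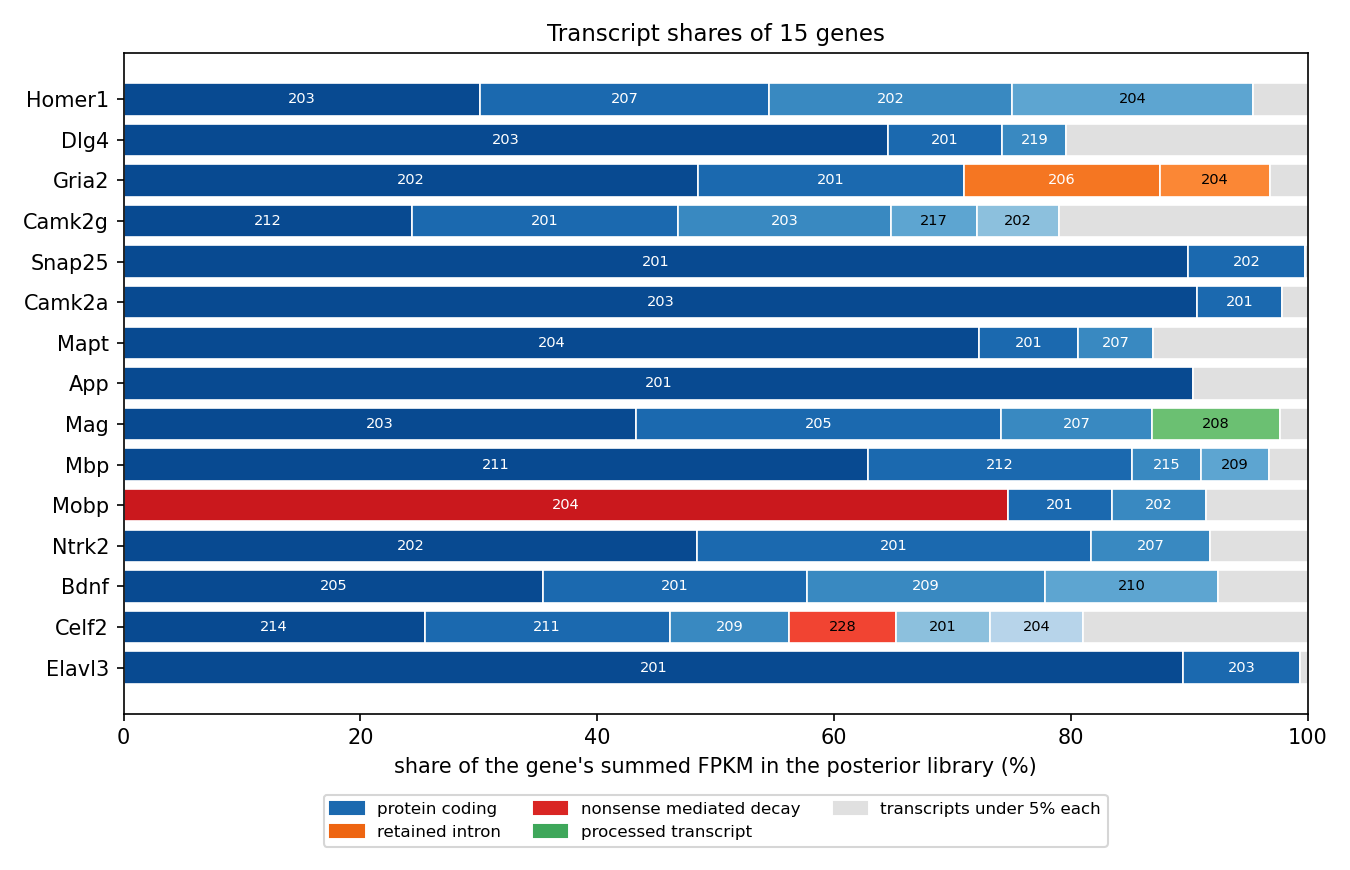
Share of each gene's summed FPKM by transcript in the posterior library, for 15 genes, with transcript numbers in the segments, colours for the annotated transcript type and grey for transcripts under 5%. Homer1 is divided among 4 transcripts of at least 10%, led by 203 with 30.1%, while Camk2a, App and Snap25 have a leading transcript of 89.9% to 90.7%.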

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

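The tests in this part were chosen after the result was seen, except the test over all genes beside a strong tail-to-tail neighbour. With 1 library per position there was no group of samples in which one stood apart, and no pair of effects to compare. What is listed first lies outside the comparisons of protein-coding genes and stands above the limit that a count of 0 allows.

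The ribosomal RNA gene CT010467.1 took 4.89% of posterior fragments and 0.0809% of anterior fragments. Of its exonic bases 73.9% lie under exons of another gene on either strand, and 37.4% on the same strand. Of its words 31.0% occur in other genes. The effect of this overlap and shared sequence on the contrast was not tested, so it is not read as a difference in ribosomal RNA content. The neuronal noncoding RNA Bc1 had 33837 posterior fragments and 0 anterior fragments. Scaled to the totals in protein-coding genes rather than to all fragments, its count was at least 3560-fold higher against a floor of 3 fragments. Malat1, a nuclear noncoding RNA, took 0.418% of posterior and 0.0967% of anterior fragments. Meg3, a maternally expressed noncoding RNA, took 0.308% of posterior and 0.201% of anterior fragments.

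Most genes that share over 50% of their words with other genes stood higher in the posterior library. Of 298 protein-coding genes with more than 50% shared words, 73.5% were at least 2-fold higher there by fragment share, against 4.77% (350) of the 7345 genes with no overlap and no shared words, all centred on the median of the 13339 genes compared, but 9.06% (27) of the 298 were at least 2-fold higher in the anterior library, against 1.93% of the 7345. Among mitochondrially encoded genes, the 5 with at least 90% shared words (mt-Co2, mt-Nd3, mt-Nd4l, mt-Co3, mt-Atp6) had a median 5.29 above that of the 6 with at most 10%, on the log2 scale. A different mitochondrial content of the tissue is argued against by the median of -0.35 of those 6, since it would move all genes of the mitochondrial genome alike. Fragments that fit several genes may have been dropped by the anterior counting and divided among the copies by Salmon, which is a candidate explanation that remains open. Exceptions by shared words are those 27 genes, mt-Nd6 (-3.53, 0% shared words) and mt-Atp8 (8.90, 0% in 204 bases). Of the mitochondrially encoded protein-coding genes only mt-Nd6 lies on the minus strand, and a part of strand in its difference was not tested. In mt-Atp8 21.1% of the exonic bases lie under another gene, so its fragments may also fit several genes.

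Of the genes with no overlap and no shared words, 27 had a fragment share at least 4-fold higher in the anterior library, led by Pter, Hipk4, Klhl34 and Il4. RNA of testis in the anterior library is argued against, since the highest FPKM there among 7 abundant spermatid transcripts was 0.144. An opposite-strand gene with at least 1000 anterior fragments ended within 5 kb of the end of 59.3% of them (16 of 27), such as Pld3, 825 bases from Hipk4, Kif3a, 1015 bases from Il4, and Cnksr2, 1067 bases from Klhl34, against 9.77% of the other 7318, although C1ql3, 2 bases from Pter, had fewer anterior fragments (3737) than Pter (6655). Fragments that run past the end of such a neighbour may thus have been counted without regard to strand. Over all 163 genes whose neighbour has at least 10 times their posterior-scaled fragments, the median lay only -0.095 from that of the 6614 without one. That met the bound of 0.1 set beforehand against such a shift. A bootstrap interval added afterwards (-0.17 to -0.024) reaches past that bound, but not as far as the value set beforehand for such a shift. The value is therefore left as undecided. Of the 163 genes 16.6% were at least 2-fold higher in the anterior library, against 1.66% of the 6614. Genes with few posterior fragments enter the 163 more easily and also count more readily as higher in the anterior library. That split therefore does not decide the question. Of the 27 genes, 11 had no neighbour of at least 1000 fragments within 5 kb.

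Lists of isocortex, striatum, hippocampus, thalamus, hypothalamus, ependyma and choroid plexus differed between the libraries. Different length definitions, overlapping genes and sequence shared between annotated transcripts are argued against as the whole cause. On the fragment share scale with only genes free of overlap and shared words, 7 of the 7 lists kept their sign. All stayed outside the middle 95% of random lists, from a median of -0.64 for isocortex to 4.27 for choroid plexus. Ependyma lay nearest the limit (2.12, percentile 97.8). By FPKM with those genes the striatal list lay inside that range (0.54, percentile 94.7). What stays open is the tissue position, which is untested, and a difference between dissections, libraries or, if they differed, animals. Differences between the quantification pipelines other than those named also stay open. These explanations cannot be told apart with 1 library per position, each with its own pipeline.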

How the results depend on the processing

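The restriction to genes without overlap or shared words was chosen after the data were seen; the other alternatives were fixed before the data were examined. There were no replicates to leave out. No paired analysis was possible because each group has 1 library. None of the 11 lists outside the range of random lists changed its sign under any alternative that gave it a value. Medians of cerebellum, interneurons, pan-neuronal, oligodendrocyte precursor, microglia and histone genes, all inside that range, changed sign under at least 1 alternative. Of the named genes, which alone were recomputed singly, only Lars2 changed sign past the 2-fold rule, to -0.48 with protein-coding transcripts only. That alternative restricted the posterior side alone, so it does not show that Lars2 was lower there. Depth limits the low genes, since 3 fragments are worth an FPKM of 0.0821 per kb in the anterior library. Where no reason is given, the cause was not tested.

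Of the 1933 genes higher in the posterior and 949 higher in the anterior library, 443 and 103 passed a 4-fold rule. The counts were 1092 and 246 by fragment share, 4486 and 170 without centring, 929 and 368 with only the 7345 genes without overlap or shared words, centred on their own median, and 423 and 135 with those genes and that centring by fragment share. With the centring of all genes, 8.92% and 9.42% of the 7345 passed by FPKM, so the own centring raises the posterior and lowers the anterior count. Without a filter 558 genes were higher in the anterior library. Pearson's r of 0.85 became 0.764 at an FPKM of at least 5, 0.928 without a filter, 0.818 and 0.860 at pseudocounts of 0.1 and 1, 0.916 by fragment share, 0.896 with genes without overlap or shared words and 0.946 with those by fragment share. Genes listed numbered 22684 (anterior) and 22673 (posterior) at an FPKM of at least 0.1, and 8395 (anterior) at 5.

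By fragment share the list medians that moved by more than the spread of random lists were choroid plexus 3.67, hypothalamus 3.12, thalamus 2.96, cholinergic 2.17, hippocampus 2.12, histones 0.96, oligodendrocytes 0.84, mitochondrial genes 0.69, oligodendrocyte precursors 0.55, cerebellum 0.30, ribosomal proteins 0.037, microglia -0.015, endothelial and mural -0.097, immediate early genes -0.36 and isocortex -0.73. With only genes without overlap or shared words they were choroid plexus 2.91, thalamus 2.75, ribosomal proteins 1.55, astrocytes 0.61, striatum 0.54, microglia -0.081 and histones -0.54 by FPKM, and choroid plexus 4.27, thalamus 3.30, hypothalamus 3.13, hippocampus 2.396, cholinergic 2.38, oligodendrocytes 0.87, oligodendrocyte precursors 0.63, astrocytes 0.61, cerebellum 0.38, ribosomal proteins 0.19, interneurons 0.16, microglia 0.055, histones 0.0036, endothelial and mural -0.076, immediate early genes -0.30 and isocortex -0.64 by fragment share. At a pseudocount of 0.1 they were choroid plexus 3.98, hypothalamus 3.21, ependymal 2.88, thalamus 2.69, cholinergic 1.98 and hippocampus 1.71, and at 1 choroid plexus 1.76 and ependymal 1.47. At an FPKM of at least 5 they were hypothalamus 4.12, ependymal 3.05, choroid plexus 2.94, meningeal 1.55, histones 1.20 and cerebellum 0.78, and without a filter ribosomal proteins 1.38, midbrain 0.22 and histones 0.0804. With protein-coding transcripts only they were ribosomal proteins 1.36 and histones 0.81. Without centring every list moved by the shift of 0.63, which exceeds the spread for all but cholinergic neurons, to choroid plexus 3.10, thalamus 2.86, hypothalamus 2.82, ependymal 2.65, hippocampus 1.95, midbrain 1.82, ribosomal proteins 1.78, striatum 1.43, blood 1.29, histones 1.16, meningeal 1.08, oligodendrocytes 0.96, astrocytes 0.83, oligodendrocyte precursors 0.71, mitochondrial genes 0.68, pan-neuronal 0.54, cerebellum 0.50, interneurons 0.45, microglia 0.21, endothelial and mural -0.078, immediate early genes -0.43 and isocortex -0.46.

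Lists that came to lie inside the range of random lists were hippocampus (percentile 95.5), midbrain (93.3), endothelial and mural (4.74) and ependymal (93.1) at an FPKM of at least 5, with 7, 3, 11 and 3 members left; midbrain (93.2) without a filter; striatum (94.7) with only genes without overlap or shared words; and endothelial and mural by fragment share (15.1). Ribosomal proteins (83.7, 4 members left) did so with both together, as did endothelial and mural (20.96). Oligodendrocytes (100), astrocytes (99.99), blood (98.2) and mitochondrial genes (100) came to lie outside it by fragment share. Others that did so were blood at an FPKM of at least 5 (97.55) and with protein-coding transcripts only (97.9); cholinergic (98.99) and histones (99.9) without a filter; histones with protein-coding transcripts only (99.5) and at a pseudocount of 1 (98.8); oligodendrocytes (97.95) and astrocytes (98.55) with genes without overlap or shared words; and cholinergic (99.04), pan-neuronal (0.575), oligodendrocytes and astrocytes with those genes by fragment share.

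With a minimum share of 25%, 3383 genes had 2 or more transcripts. The median leading share became 67.2% at a gene FPKM of at least 5, 78.0% with protein-coding transcripts only and 82.0% by fragments. By list it became, in percent, trophic factors 62.1, receptors and channels 57.9, splicing regulators 56.4 and cytoskeleton 47.8 with protein-coding transcripts only, and trophic factors 74.5, receptors and channels 72.0, splicing regulators 57.5 and cytoskeleton 47.6 by fragments. The list of synaptic adhesion and scaffolding came to lie below the range of random lists with protein-coding transcripts only (45.5, percentile 1.31, lower limit 47.0) and by fragments (47.4, percentile 0.73, lower limit 50.5), and cytoskeleton by fragments (percentile 0.75, lower limit 50.2). By fragments retained-intron transcripts took 3.07% and nonsense mediated decay transcripts 2.42%.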

Other observations

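The tests and counts in this part were chosen after the data were seen.

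Outside the marker lists, the genes named next have no overlap and no shared words and were chosen for their differences after the values were seen. Higher in the posterior library were Dlk1, an imprinted gene of the Notch ligand family, with an FPKM of 0.368 against 17.8 and a fragment share 27.9-fold higher (95% interval 22.3 to 35.5), Agt, the precursor of angiotensin made by astrocytes, with 1.98 against 34.4 and 18.7-fold (15.8 to 22.3), Arhgap36 with 0.112 against 9.03 and 59.1-fold (35.2 to 108), and Tnnt1 with 0.721 against 25.2 and 12.8-fold (9.88 to 16.9). Lcn2, an iron-binding acute-phase protein, had 4 anterior and 1007 posterior fragments, a ratio of 79.5 (30.9 to 292). Wdr74 had 0 anterior and 2209 posterior fragments, at least 232-fold higher. Whether its count of 0 comes from the tissue or from the counting was not tested. Higher in the anterior library were Htr2a, the serotonin 2A receptor, with 19.1 against 5.17 and a share 3.07-fold higher (2.93 to 3.20), Ephb6 with 83.1 against 23.1 and 3.17-fold (3.09 to 3.25), Dkk3 with 211 against 69.6 and 2.61-fold (2.57 to 2.66), and Nxph3 with 28.6 against 9.57 and 2.73-fold (2.58 to 2.89). Cck, a neuropeptide of cortical neurons, had 348 against 401, but a share 2.24-fold higher in the anterior library (2.19 to 2.28).

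In the posterior library 8119 protein-coding genes had 2 or more transcripts at 10% of the gene. In 4467 of them both leading transcripts were protein coding with a coding part in M21, and in 3492 (78.2%) the coding parts differed, while 975 (21.8%) had the same coding part. Of those 975, the ends at the 3' side lay more than 100 bases apart in 444 (45.5%) and the starts at the 5' side in 551 (56.5%). In 1848 genes a retained-intron transcript was among the leading pair, and in 636 a transcript subject to nonsense mediated decay. Coding parts in the annotation can be incomplete, which counts them as different.

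A retained-intron transcript led in 348 protein-coding genes (2.91%), and a transcript subject to nonsense mediated decay in 188 (1.57%). The most abundant genes led by a retained-intron transcript were Prkcb, a protein kinase C of neurons, with Prkcb-208 at 50.1%, Ghitm with Ghitm-203 at 44.8%, Rps16 with Rps16-203 at 72.0% and Ank2 with Ank2-216 at 24.1%.

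Overlap between genes went with the same side as shared sequence. Exons that overlap on the same strand also share words, so the classes of same-strand overlap and of shared words are not independent. Of 176 protein-coding genes with more than 50% of their exonic bases under another gene of the same strand, 84.1% were at least 2-fold higher in the posterior library by fragment share, and of 598 with more than 20% overlap on the opposite strand alone, 21.7% were. The share was 8.19% over all 13339 genes compared and 4.77% over the 7345 without overlap or shared words. At least 2-fold higher in the anterior library were 1.14% of the 176, 1.51% of the 598 and 1.84% of the 13339.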
